A study of Mus with 6 samples.

How the data were processed

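Gene expression was measured by RNA sequencing of total RNA, extracted with Trizol, from 6 samples of 4T1, a mouse mammary carcinoma cell line. Per the labels, 3 samples were untreated and 3 received isopimaric acid (IPA), a plant diterpene acid, at 10 µg/mL for 24 h. Groups and replicate numbers were taken from the sample titles. The columns of the treated samples carry a shorter abbreviation than the titles and were matched to them by letter and number. The sources used here do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

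The deposited values are raw read counts per Ensembl gene ID, whole numbers for 35304 IDs in each of the 6 samples, per the file headers and values. The submitters' processing notes name the genome builds GRCm38 and mm10. The aligner, the counting tool, the annotation release and the handling of strand and of multiply mapped reads are not given in the sources used here. The smallest total count of any ID over the 6 samples was 7, so IDs with no reads are not among those analysed here. The files do not pair the IDs with gene names. The reference table at hand, of 49997 genes, has 0 rows with an Ensembl ID, so 0 IDs were matched to a name. For this reason the 36 gene lists fixed by symbol before the data were examined, covering calcium handling, oxidative phosphorylation, ion channels, proliferation, invasion, stress responses and markers of other cell types, were not analysed here, nor was the share of mitochondrially encoded genes. Checks of GC content and gene length were not made, for lack of a value for any ID.

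Counts were compared with the quasi-likelihood F-test of edgeR 4.0.16 (robust fit) in R 4.3.3, with TMM normalization and the filterByExpr filter, which kept 24935 IDs. P-values were adjusted by Benjamini-Hochberg, and an ID was called at an adjusted p under 0.05, with a further count at a fold of 2 or more. Fold changes are IPA relative to untreated, and the standard error of a log2 fold change was obtained by dividing it by the square root of F. Correlations and principal components used log2 CPM with a prior count of 2, over the same IDs. CPM values given per library were computed from the deposited counts and the library totals, without TMM factors.

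The rule for named genes, set before the data were examined, took the largest fold changes among called genes with a mean CPM of at least 5, groups that did not overlap in CPM, and a symbol. It named no gene, since no ID was called in the comparison of all 6 samples. In its place, the 2 IDs with the largest increase and the 2 with the largest decrease were taken by the same conditions, without the symbol, from the comparison that leaves out untreated replicate 2. These 4 IDs were chosen after their values were seen.

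In place of the lists by symbol, 3 cell-cycle lists by Ensembl ID were made from the mouse phase marker pairs of scran 1.30.0. They hold the genes that were the higher member in at least 90% of at least 20 pairs of their phase. The G1 list has 121 genes, the S list 80 and the G2M list 93; 2 are shared by G1 and S, 2 by G1 and G2M, and 3 by S and G2M. They were chosen after the files had been examined and before their own values had been seen. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, and beside it with an estimated correlation and with fry.

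The depth of the libraries ranged from 3410411 to 58924711 counts. The level that 3 counts correspond to was 0.0509 CPM in the deepest library and 0.88 CPM in the shallowest. These floors cover counting error only. No 2 replicates agreed within sampling noise: the chi-square per degree of freedom within a group was lowest, at 6.56, between IPA replicates 1 and 2. This measure grows with depth, and that pair includes the shallowest library, so it does not rank the replicates by agreement. IPA replicates 2 and 3, at 13.3, had the higher correlation in log2 CPM, 0.987 against 0.935.

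The edgeR procedure was tested on simulated counts with the depths of the real libraries and the mean and dispersion of each ID. Mean and dispersion were common to all libraries, so no simulated library was an outlier as untreated replicate 2 was. Changes were set only in IDs with a mean of at least 5 CPM, so recovery at lower levels was not tested. For the comparison of all 6 libraries, over 24935 IDs, it recovered 0 of 100 changes of 2-fold and 8 of 100 changes of 4-fold, with 1 false call. For the comparison without untreated replicate 2, over 25592 IDs, it recovered 75 of 100 changes of 2-fold and 100 of 100 changes of 4-fold, with 19 false calls.

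Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom, other normalization factors, other filters on low counts, the replicate number as a block, and leaving out each sample in turn. Leaving out mitochondrially encoded genes was also set but was not run, since the sources used here do not say which IDs these are. Combinations with untreated replicate 2 left out, sample quality weights, and 1 ID per set of IDs with near-identical counts were added after the data had been examined.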

Results

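The data set comprised 6 RNA-seq libraries of 4T1 cells, a mouse mammary carcinoma line. There were 3 untreated samples and 3 samples exposed to 10 µg/mL isopimaric acid (IPA) for 24 h. Total counts per library were 20257983, 58924711 and 52870190 for untreated replicates 1, 2 and 3, and 3410411, 43593509 and 41029847 for IPA replicates 1, 2 and 3. The deepest library thus held 17.3 times the counts of the shallowest. Expression was recorded as read counts for 35304 Ensembl gene IDs, of which 24935 passed the filter on low counts.

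The main differences between libraries did not follow the 2 groups of the design. Untreated replicate 2 stood apart from the other 5 libraries: its correlation in log2 CPM was 0.81 with untreated replicate 1, 0.811 with untreated replicate 3, and between 0.779 and 0.807 with the IPA libraries. These correlations are across genes, which are not independent replicates. Among the other 5 libraries the correlations ran from 0.922 to 0.987. The first principal component held 66% of the variance and separated untreated replicate 2 from the rest. The second held 22.8% and separated IPA replicate 1, the shallowest library. Untreated replicates 1 and 3 and IPA replicates 2 and 3 lay close together, with correlations of at least 0.968.

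**Figure D1:**
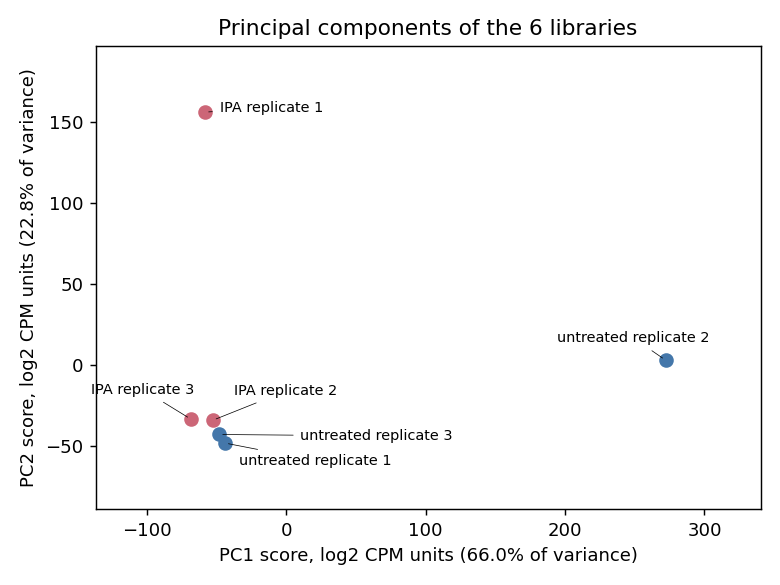
Scores of the 6 libraries on the first and second principal components of log2 CPM, with untreated samples in blue and IPA samples in red, 1 point per library. Untreated replicate 2 lies alone at a score of 272 on the first component, and IPA replicate 1 lies alone at 155.9 on the second.

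The comparison of treated with untreated cells asks which genes respond to IPA, which the series title describes as an ion channel regulator acting on calcium and oxidative phosphorylation pathways. Over all 6 libraries, edgeR called 0 IDs higher and 0 IDs lower with IPA at an adjusted p under 0.05, and therefore 0 in either direction at a fold of 2 or more. At an unadjusted p under 0.05 there were 1560 of the 24935 IDs, or 6.26%. DESeq2 on the same 6 libraries called 22 IDs higher and 63 lower, while limma-voom called 0. The smallest adjusted p in the edgeR comparison was 0.0746, for ENSMUSG00000023045. The biological coefficient of variation was 0.57.

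The outcome depended on untreated replicate 2. Without it, edgeR called 322 IDs higher and 564 lower with IPA out of 25592 tested, of which 56 and 277 changed by a fold of 2 or more, and the biological coefficient of variation was 0.178. That comparison sets 2 untreated libraries against 3 IPA libraries. The median log2 fold change was 0.72 among the 322 higher IDs and -0.98 among the 564 lower IDs. Of the 886 called IDs, 874 were also tested over all 6 libraries, and 854 of these had the same sign of fold change there, an agreement that is in large part built in, since the comparisons share 5 libraries and the IDs were chosen by their calls in one of them. Leaving out any of the other 5 libraries in turn gave 0 calls in either direction. With library totals in place of TMM, the comparison without untreated replicate 2 gave 691 higher and 327 lower IDs, so that the higher share moved from 36.3% to 67.9%, and the median log2 fold change over all tested IDs moved from -0.04 to 0.06.

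The files do not pair the IDs with gene names, so 4 IDs are given as examples. In the comparison without untreated replicate 2, ENSMUSG00000023045 rose by a log2 fold change of 4.58 ± 0.29 (SE; edgeR adjusted p = 5.73e-09). Its level was 0.925 ± 0.187 CPM in untreated cells and 23.5 ± 2.71 CPM with IPA (SD, n = 3 each). These CPM levels, and those of the other 3 IDs, include untreated replicate 2 and no TMM factors, so their ratio differs from the fitted fold change. ENSMUSG00000038742 rose by 2.73 ± 0.20 on the log2 scale in that comparison (edgeR adjusted p = 6.09e-08). Its level over all 6 libraries was 7.07 ± 1.16 CPM in untreated cells and 48.6 ± 3.44 CPM with IPA. ENSMUSG00000038418 fell by 4.48 ± 0.39 on the log2 scale in that comparison (edgeR adjusted p = 1.46e-05). Over all 6 libraries it stood at 19.4 ± 3.51 CPM in untreated cells and 1.38 ± 0.954 CPM with IPA. It had 8, 59 and 18 counts in IPA replicates 1, 2 and 3, so the size of its fall rests on few reads. ENSMUSG00000064370, an abundant ID, fell by 3.17 ± 0.19 on the log2 scale in that comparison (edgeR adjusted p = 3.36e-09). Over all 6 libraries it stood at 2791 ± 1506 CPM in untreated cells, where replicate 2 had 1143 CPM, and at 436 ± 108 CPM with IPA. The CPM values of untreated and IPA libraries did not overlap for any of the 4, a condition of their choice. Over all 6 libraries the log2 fold changes of the same 4 IDs, in the same order, were 4.43, 2.53, -4.23 and -2.84, with edgeR adjusted p-values of 0.0746, 0.493, 0.657 and 0.657.

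**Figure D2:**
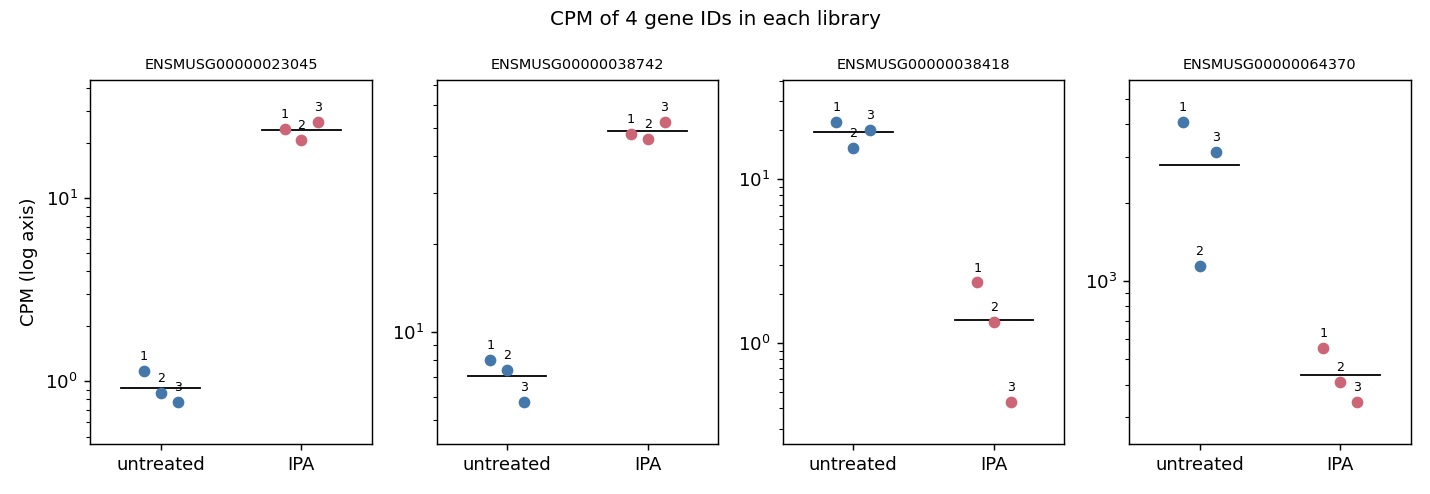
CPM (log axis, a different range in each panel) of 4 gene IDs in the 3 untreated libraries (blue) and the 3 IPA libraries (red), numbered by replicate, with lines at the group means. The first 2 IDs lie higher in every IPA library than in every untreated library and the last 2 lie lower, and for ENSMUSG00000064370 untreated replicate 2, at 1143 CPM, is nearer to the IPA libraries than the other untreated libraries are.

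The 50 most abundant IDs were lower with IPA more often than the rest, a grouping of IDs chosen after the values were seen. Of the 50 IDs with the highest mean CPM, 17 were lower with IPA and 2 were higher in the comparison without untreated replicate 2 (edgeR). Among all other tested IDs 2.14% were lower, against 34% of these 50. With 1 ID kept per set of near-identical counts, 15 of 48 were lower. Which genes the 17 are was not determined here. They may share reads or vary together, so these shares do not count independent genes. The log2 fold changes of the 17 ran from -3.17 to -1.40. Together they took 11.1%, 11.1% and 8.03% of the counts of untreated replicates 1, 2 and 3, and 3.75%, 2.69% and 2.32% of the counts of IPA replicates 1, 2 and 3. Over all 6 libraries none of the 17 passed the edgeR test, the smallest adjusted p being 0.657, while their median log2 fold change was -2.14, against -1.99 without untreated replicate 2. The IDs were chosen on 5 of these libraries, so the sign of that median is in large part fixed by the choice.

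The share of counts in each library's own 10 most abundant IDs was 10.8 ± 1.14% in untreated samples and 6.6 ± 0.288% in IPA samples (SD, n = 3 each). The difference of -4.18 percentage points had a two-sided p of 0.1 in an exact permutation test, the smallest that 3 samples against 3 can give.

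Cell-cycle marker lists bear on proliferation, which the series title names. Over all 6 libraries, 0 of the 118 tested G1 markers, 0 of the 79 S markers and 0 of the 92 G2M markers passed the edgeR test, over all genes or adjusted over the list alone. The mean log2 difference was -0.12 for G1 markers, 0.01 for S markers and -0.09 for G2M markers, with limma camera adjusted p-values of 0.576, 0.686 and 0.576. The median of the S markers, at -0.003, had the opposite sign to their mean. Without untreated replicate 2, the mean log2 difference of the G2M markers was -0.14; 0 of the 92 were higher and 6 lower over all genes, and 3 were higher and 11 lower when adjusted over the list alone. Of the G1 markers 2 were higher and 3 lower over all genes, and 3 and 7 when adjusted over the list alone; of the S markers 1 was higher and 2 lower, and 3 and 4 when adjusted over the list alone. The limma camera adjusted p of the G2M list was 0.154, and 0.338 with an estimated correlation. The self-contained fry test of limma, which asks whether the list moves on balance one way, gave an adjusted p of 0.016 for the G2M list, 0.272 for the G1 list and 0.4 for the S list. Without IPA replicate 1 as well, fry gave 0.254 for the G2M list.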

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

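Settings that leave out untreated replicate 2 together with another change, sample quality weights, 1 ID per near-identical set, and the cell-cycle lists were chosen after the data had been examined. Over all 6 samples the counts of higher and lower IDs stayed at 0 with limma-voom, RLE factors, upper-quartile factors, a filter of at least 1 CPM in at least 3 samples, and 1 ID per near-identical set. DESeq2 called 22 higher and 63 lower, 20 and 63 at a fold of 2 or more, with 16165 of 34648 IDs given no adjusted p; 84 of these 85 calls were among the 886 made by edgeR without untreated replicate 2, on 5 of the same libraries. Library totals and no filter on low counts each called 1 ID, at a fold of 2 or more, ENSMUSG00000023045, with adjusted p-values of 0.0423 and 0.0387. Limma-voom with sample quality weights, which gave untreated replicate 2 a weight of 0.0388, called 492 higher and 755 lower, 92 and 363 at a fold of 2 or more. Leaving out 1 sample at a time gave 0 to 322 higher and 0 to 564 lower IDs, 0 to 56 and 0 to 277 at a fold of 2 or more, and every count above 0 came from leaving out untreated replicate 2.

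Without untreated replicate 2 and IPA replicate 1 together there were 719 higher and 763 lower IDs, 166 and 416 at a fold of 2 or more, and 806 of the 886 calls were shared, on 4 of the same libraries. With untreated replicate 2 left out, DESeq2 gave 634 and 661 (77 and 217 at a fold of 2 or more), limma-voom 660 and 1009 (93 and 407), library totals 691 and 327 (117 and 194), upper-quartile factors 309 and 581 (50 and 278), and RLE factors 364 and 481 (64 and 248). Beyond leaving out that library, the cause of these differences was not tested. Of 22 alternatives, ENSMUSG00000023045 passed in 11 and each of the other 3 named IDs in 9, with adjusted p-values from 8.16e-59 to 0.998. Their direction was not open to these alternatives, since the 4 were chosen for groups that do not overlap.

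With the replicate block the count was 0 in both directions. The deviations of same-numbered samples correlated at -0.0771, 0.0183 and 0.161, and 3 of the 6 samples correlated best with the sample of their own number. The numbers were therefore not taken to pair the samples; untreated replicate 2 and IPA replicate 1 weigh heavily in these deviations, and a shared batch or day is not excluded. No cell-cycle list passed camera or fry over all 6 samples, nor camera with any sample left out. With library totals the mean log2 differences of G1, S and G2M markers were 0.11, 0.24 and 0.14, against -0.12, 0.01 and -0.09 in the main comparison. With 1 sample left out, that of G1 markers ran from -0.169 without untreated replicate 3 to -0.0594 without untreated replicate 2. For G2M markers it ran from -0.136 without untreated replicate 2 to -0.02 without untreated replicate 1, and was -0.0404 without untreated replicate 3. For S markers the differences were -0.0294 with upper-quartile factors and -0.0125 with the filter at 1 CPM, and from -0.048 without untreated replicate 2 to 0.0724 without untreated replicate 1 when 1 sample was left out (-0.0382 without IPA replicate 3), and none passed. The difference in the share of the most abundant IDs was -5.53 percentage points for the top 20 and -7.03 for the top 50. Depth limits IPA replicate 1 most, where 3 counts correspond to 0.88 CPM. The 36 lists by symbol and the setting without mitochondrially encoded genes were not run.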

Other observations

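All tests on untreated replicate 2 and on the abundant IDs, and the splits behind the counts of 0, were chosen after the results they bear on were seen. The thinning test of IPA replicate 1, the splits of 5 libraries and the splits for the cell-cycle lists were chosen before theirs were seen.

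Some IDs had near-identical counts. Among 13888 IDs with a mean count of at least 100 and at least 10 counts in each library, 221 pairs agreed within 2% in every library, against 0 pairs after counts were shuffled among IDs of similar abundance. They formed 66 sets of 154 IDs, the largest of 18 IDs, and held 4.1% of all counts. The values of such IDs are uncertain, since the same reads could have been counted for several of them; 88.2% of the lowered abundant IDs are left when 1 ID is kept per set.

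Untreated replicate 2 differed from every other library. A swap with a treated sample is argued against: over 874 IDs called between the other 5 libraries, its position between the untreated mean at 0 and the IPA mean at 1 was 0.0798 ± 0.0532 (bootstrap SE over genes). Such an SE treats genes as independent and does not measure the spread between libraries. Too few starting molecules fit part of the pattern. The interquartile range of its log2 gene ratios narrowed from 2.08 at 1 to 3 CPM to 1.28 at 100 to 300 CPM, and 16.9% of IDs at 1 to 3 CPM had 0 counts. The narrowing is not particular to this library, since the range between untreated replicates 1 and 3 went from 0.642 to 0.385 over the same levels. Too few molecules are argued against as the whole cause by the range of 1.83 at 300 CPM or more, wider by 0.558 ± 0.124 (bootstrap SE over genes). That range was 3.87 times the one between untreated replicates 1 and 3, which also widened there, to 0.474. RNA of other cells added to that of the untreated cells was not settled. Of 3594 IDs at 3 to 10 CPM in untreated replicates 1 and 3, 5.09% had 0 counts in untreated replicate 2, against 0.278% in IPA replicate 1. If zeros came from read depth alone, the untreated cells gave under 5.79% of its counts, which is what IPA replicate 1 has in all. Too few starting molecules would also give zeros, with or without added RNA, so this test cannot decide. A library partly or almost wholly from other cells, or from cells in a different state, stays open, and markers of other cells were not analysed here.

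The lower level of 17 of the 50 most abundant IDs with IPA, found without untreated replicate 2, is a hypothesis about the treated cells. Reads counted for several IDs stay open as a cause. With 1 ID kept per near-identical set 88.2% of the 17 were left, but this only removed IDs from the list. The counts of the IDs kept were not changed, and IDs that share only part of their reads need not form such sets. The choice among 4 normalizations made little difference, with a median log2 change of the 17 of at most -1.88 under each. These settings could not have removed the fall, since the median over all tested IDs only ran from -0.05 with upper-quartile factors to 0.06 with library totals. Normalization as a cause is therefore not decided by this test. Other forms of normalization were not tested. Without IPA replicate 1, 17 of 17 passed, which was likely in advance, since the 17 were chosen partly on the libraries that were left. IPA replicate 1 alone is argued against by the shares of counts that the 17 took. These were 2.69% and 2.32% in IPA replicates 2 and 3, below the 3.75% of IPA replicate 1. Differences in RNA quality or in the handling of the untreated samples were not tested and stay open beside an effect of IPA.

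IPA replicate 1 may stand apart because of its depth. With the other libraries thinned to its 3410411 counts, the correlation of IPA replicates 2 and 3 fell from 0.987 to 0.98, and that of IPA replicate 1 with them, 0.933 before thinning, was 0.968. The difference was then 0.0123, within the bound of 0.02.

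The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. For the counts of higher and lower IDs, at any fold or at a fold of 2 or more, the real value was 0 and the highest of the other splits was 0. A real value of 0 fixes the outcome that 10 of 10 splits give as many, so this count tests nothing. The 5 samples without untreated replicate 2 also make 10 splits, of which 1, the real one, gave as many as 886 calls, and the highest of the others gave 79. A camera p as small as the real one arose in 9 of 10 splits for G1 markers (real 0.384, smallest other 0.0375), in 5 for S markers (0.686 and 0.403) and in 1 for G2M markers (0.347 and 0.377).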
